A study of Mus musculus with 12 samples.

How the data were processed

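Small RNA was sequenced from kidneys of untreated wild-type mice at postnatal day 0 and day 8, with 6 libraries at each age. Per the labels' protocols, total RNA that kept the small fraction was purified with a NucleoSpin miRNA kit, and libraries were made with the QIAseq miRNA Library Kit. FastQC is named per the submitters' processing notes. The aligner, the genome build, the miRBase release, any use of molecular identifiers and any filter on reads are not given in the sources used here. Libraries were assigned to an age by the age label of each sample, and replicates were numbered 1 to 6 within an age in the order of the series. The labels give no batch, litter or sex. Each sample title carries its own number, but what it stands for is not given. Every day 0 number is lower than every day 8 number, so an order they may mark cannot be told apart from age. Nothing therefore states that the 6 libraries of an age came from separate animals. The p-values therefore measure only the spread between these samples, part of which may be technical.

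The authors deposited 1 table of 1652 mature miRNA names in CPM (counts scaled to a common total), in which each library sums to 1000000. Its name speaks of raw counts, but the values are not whole. Within each library they are whole multiples of the value of 1 read, and 100.0% of the values came out whole within 0.001 of a read. Recovered in this way, the libraries hold between 3.37 and 11.8 M miRNA reads (M, 1000000). Reads without known use of molecular identifiers are not independent molecules, so limits from read numbers cover counting error only. No library was a copy of another: the lowest chi-square per degree of freedom between libraries of the same age was 50.9. All 12 columns of the table were used.

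The design fixed before the data were examined named edgeR for counts and limma for CPM, so the CPM branch was used. The main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(CPM + 1), for names with a CPM of at least 1 in at least 6 libraries. This left 564 of 1652 names, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. A log2 change is always day 8 minus day 0 on the log2(CPM + 1) scale, which understates the change of low names, and SE is its standard error from limma. CPM is relative to the library total, so a change is a change of share and not of molecules per cell. Each title miRNA was also tested by a two-sided exact permutation test of its CPM over 924 assignments, where the smallest possible p is 0.00216. The share of counts in the 10 most abundant names was compared in the same way. Arm balance was tested with limma on the log2 ratio of 5p to 3p CPM, each plus 1, for hairpins with both arms at a mean CPM of at least 20.

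In all, 18 lists of miRNAs were fixed before the data were examined. They cover the title miRNAs, the Dlk1-Dio3 cluster, other imprinted loci, the let-7, miR-30 and miR-200 families, the families of miR-34 with miR-449 and of miR-192 with miR-194 and miR-215, the miR-17-92 cluster with its paralogs, the cluster of miR-322 and miR-503, miRNAs within Hox clusters, and markers of mesenchymal, endothelial, erythroid, leukocyte, striated muscle and other organ cells. A further list holds miR-124-3p and miR-135a-5p, known from reporter assays on the mineralocorticoid receptor 3′ UTR. Lists with more than 1 tested member were compared with all other names by camera at a preset correlation of 0.01, with an estimated correlation and the fry test beside it, adjusted over 17 lists. Each list is given with its calls over all names tested and with its calls adjusted over the list alone. Members were matched by name without the arm, so both arms of a hairpin can count as members, and these are not independent. Names with a locus number, such as miR-92a-1-5p or those of miR-30c-1 and miR-194-2, therefore count in no list.

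The named miRNAs follow a rule fixed in advance: both title miRNAs; the 10 largest rises and 10 largest falls among names past the threshold with a mean CPM of at least 100 and no overlap between the ages; the 5 most abundant names; and up to 4 of the most abundant members of each list. Of the names that met the second part, 39 rose and 79 fell. Any other name in the text was chosen after its values were seen.

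Positions are from the GENCODE M21 annotation of GRCm38, matched by gene symbol. The build the authors used is not known, and 366 of the 401 hairpin names tested had an annotated locus. A mature miRNA made from several loci, or sharing most of its sequence with another family member, cannot be split between them with these values.

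Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, and edgeR 4.0.16 with RLE, upper quartile or total count scaling on the recovered reads, other filters, pseudocounts of 0.1 and 5, a fold of at least 2, each library left out in turn, other list tests, and other minimums for the arm test. Added after the data were seen were edgeR with TMM scaling on the recovered reads, CPM rescaled by TMM or RLE factors, and a fit without day 0 replicate 6 and day 8 replicate 3, the 2 libraries farthest from their groups. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.

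The tests were checked on simulated counts for day 8 against day 0 over 564 miRNAs, with 200 names changed. limma recovered 48.5% of the names changed by a log2 of 0.5, 83.6% of those changed by 1 and 97.0% of those changed by 2. Of its 157 calls, 4 were unchanged names, and it made 0 calls when no name was changed. The simulated list was called and 0 other lists were. The simulation drew each name independently and changed about as many names up as down. It therefore checked neither the scaling under an excess of falls nor the list test when members of a list vary together. The arm test recovered 18 of 20 changed hairpins, with 0 false calls among the unchanged ones of the 71 hairpins tested.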

Results

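The series measured mature miRNAs in neonatal mouse kidney, in 6 libraries at day 0 and 6 at day 8. Its stated purpose was to find miRNAs that change over this period and that could act on the mineralocorticoid receptor, the aldosterone receptor encoded by Nr3c2. The title names miR-409-3p and miR-431-5p. The day 0 libraries held 7.10 ± 2.04 M miRNA reads (M, 1000000; SD, n = 6; 3.37 to 9.05) and the day 8 libraries 9.53 ± 2.58 M (SD, n = 6; 5.16 to 11.8). The names seen at least once numbered 1037 ± 57.3 at day 0 and 1027 ± 27.0 at day 8. The first principal component of log2(CPM + 1) held 68.5% of the variance and separated the ages, while the second held 10.4%. Day 0 replicate 6, the library with the fewest reads, lay at -12.6 on the second component and day 8 replicate 3 at -6.46, against values from -2.46 to 5.12 in the other 10 libraries.

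The question of the first comparison was which miRNAs differ between the ages. At day 8 the kidney libraries held more of miR-192-5p, miR-194-5p, miR-204-5p and most members of the miR-30 family. They held less of miRNAs of the imprinted Dlk1-Dio3 cluster, of miR-130b-3p, and of the muscle-specific miR-206-3p and the liver-specific miR-122-5p. Whether miR-206-3p and miR-122-5p came from kidney cells or from other tissue carried along was not tested. The cell types behind the higher miRNAs were not measured either. miR-802-5p rose most among the named miRNAs, from 30.8 ± 7.56 to 182 ± 35.2 CPM (SD, n = 6 at each age), a log2 change of 2.54. miR-192-5p rose from 3112 ± 462 to 10948.5 ± 821 CPM, or 3.52-fold, and miR-194-5p from 1790 ± 195 to 5917 ± 494 CPM, or 3.31-fold. miR-30e-5p rose from 3891 ± 460 to 12648 ± 1389 CPM and miR-30a-5p from 6542 ± 621 to 16994 ± 693 CPM.

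The remaining large rises were those of miR-190a-5p (log2 change 1.67), miR-204-5p (1.49), miR-101b-3p (1.47), miR-30d-5p (1.45) and miR-195a-5p (1.35). miR-206-3p fell from 217 ± 131 to 6.79 ± 2.26 CPM (SD, n = 6), a log2 change of -4.54. miR-122-5p fell from 1794 ± 1275 to 140 ± 130 CPM, a log2 change of -3.91. Their SDs at day 0 were large because libraries ranged from 52.5 to 388 CPM for miR-206-3p and from 478 to 3284 CPM for miR-122-5p. miR-92a-1-5p fell from 198 ± 21.4 to 30.5 ± 3.34 CPM, and miR-130b-3p from 803 ± 107 to 178 ± 29.2 CPM. The other large falls were in the Dlk1-Dio3 cluster: both title miRNAs, miR-541-5p (-2.40), miR-134-5p (-2.39), miR-300-3p (-2.27) and miR-369-3p (-2.11). For every miRNA named so far as risen or fallen, the 6 libraries of the higher age all lay above the 6 of the other, and limma gave adjusted p-values from 2.5e-10 (miR-92a-1-5p) to 0.000169 (miR-122-5p).

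In all, limma called 365 of 564 miRNAs, 93 higher and 272 lower at day 8, and 162 of these changed at least 2-fold (25 higher, 137 lower). Of the calls, 259 had no overlap between the libraries of the 2 ages, against 0.216% of names by chance. The median log2 change of all 564 was -0.34. Rescaling CPM by TMM factors, which were 1.15 ± 0.0380 at day 0 and 0.874 ± 0.0390 at day 8, moved that median to -0.00 and gave 171 higher and 193 lower calls, of which 286 were shared with the main test and 0 had the opposite direction. With upper quartile factors in edgeR 213 were higher and 155 lower, with 253 shared and 7 in the opposite direction. Small decreases are therefore reported relative to the library total only.

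Among the 5 most abundant miRNAs the changes were small, and the direction of miR-16-5p, miR-10a-5p and miR-26a-5p turned with the scaling. miR-126a-3p, an endothelial miRNA, rose from 86105 ± 4013 to 102744 ± 5723 CPM (SD, n = 6; log2 change 0.25, and 0.64 with TMM factors). miR-16-5p fell from 80219 ± 3017 to 67092 ± 4762 CPM (-0.26), and its change was 0.13 with TMM factors, not past the threshold. miR-10a-5p had a log2 change of -0.24 (limma adjusted p = 0.0427), and 0.15 with TMM factors, not past the threshold. That call was also lost without any one of day 0 replicates 1, 4, 5 or 6 or day 8 replicates 1, 4, 5 or 6, where the log2 changes ran from -0.24 to -0.20. let-7f-5p (0.11) and miR-26a-5p (-0.20) did not pass the threshold, and with TMM factors their changes were 0.50 and 0.19, of which let-7f-5p passed. Without day 0 replicate 1 both passed, at 0.15 and -0.27.

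**Figure D1:**
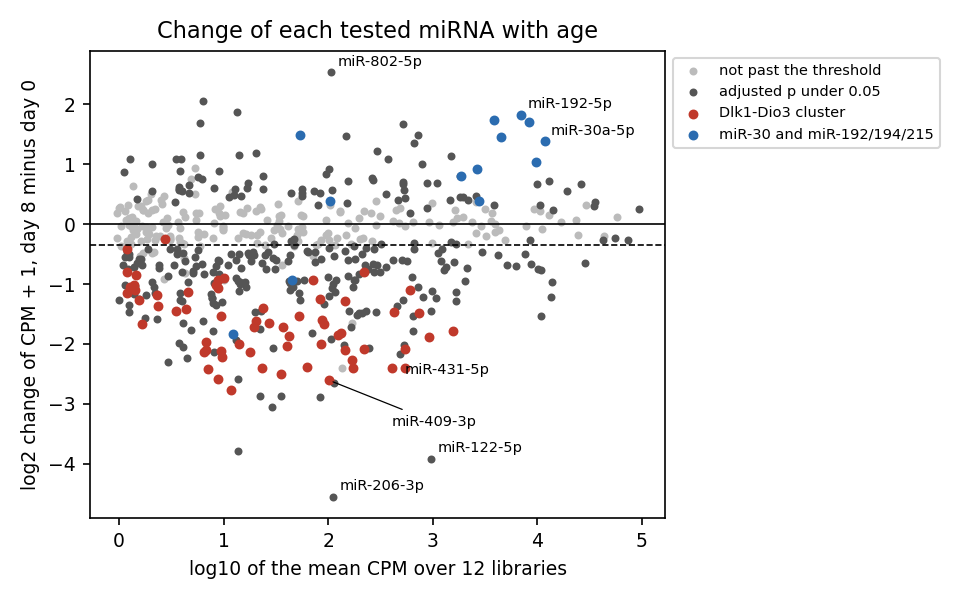
Log2 change of CPM + 1 from day 0 to day 8 (y axis, n = 6 libraries at each age) against the log10 of the mean CPM over 12 libraries (x axis), with 1 point for each of 564 miRNAs, where dark grey points had an adjusted p under 0.05 in limma and light grey points did not, red and blue points are list members whatever their p, and the dashed line is the median change of all miRNAs, -0.34. The red points of the Dlk1-Dio3 cluster lie below 0, while most blue points of the miR-30 and miR-192, miR-194 and miR-215 families lie above it.

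The second comparison concerned the title miRNAs. Both were lower at day 8. miR-409-3p fell from 176 ± 31.6 to 28.1 ± 5.13 CPM (SD, n = 6 at each age), or 6.27-fold, with a log2 change of -2.61 (SE 0.147) and a limma adjusted p of 2.8e-09. miR-431-5p fell from 686 ± 142 to 129.9 ± 30.3 CPM, or 5.28-fold, with a log2 change of -2.39 (SE 0.166) and a limma adjusted p of 1.6e-08. For each, all 6 day 0 libraries lay above all 6 day 8 libraries, and the exact permutation p was 0.00216, the smallest this design can give. With TMM factors the log2 changes were -2.22 and -2.01. Between 175 and 1980 reads per library lay behind miR-409-3p and between 842 and 7762 behind miR-431-5p. Ranked by mean CPM, miR-409-3p went from place 188 to 276 and miR-431-5p from 109 to 174. The study chose these miRNAs with the help of this comparison, so their fall is not independent evidence.

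The hairpin of miR-409 lies on chromosome 12 at 109743158 to 109743236 (GRCm38, plus strand), in an intron of the long non-coding gene Mirg on the same strand. The hairpin of miR-431 lies on chromosome 12 at 109590447 to 109590537 on the plus strand, in an exon of the protein-coding gene Rtl1, which is transcribed from the opposite strand. Of the miRNAs known from reporter assays on the receptor's 3′ UTR, miR-135a-5p fell from 856 ± 67.7 to 215.4 ± 55.8 CPM (SD, n = 6), a log2 change of -2.02 with a limma adjusted p of 4.5e-08. It was the 1 tested member of its list, and the count was the same adjusted over the list alone. miR-124-3p did not reach the minimum CPM.

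**Figure D2:**
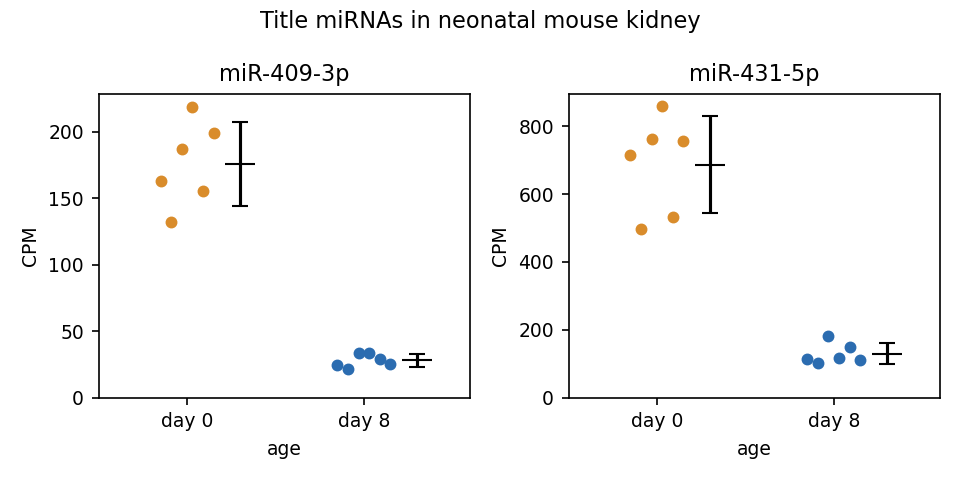
CPM (y axis) of miR-409-3p and miR-431-5p by age (x axis), with 1 point for each of 6 libraries and a bar beside them for the mean ± SD. All day 0 libraries lie above all day 8 libraries, with means of 176 and 28.1 CPM for miR-409-3p and 686 and 129.9 CPM for miR-431-5p.

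The third comparison took the fixed lists. miRNAs of the Dlk1-Dio3 cluster, which are made from the maternal chromosome, fell together: 61 of 63 tested members were lower, 0 were higher, and 62 were lower when adjusted over the list alone. The 63 members are arms of 42 hairpins, so the counts are not of independent miRNAs. The median log2 change was -1.66. The summed CPM of the cluster went from 12617 ± 2116 to 3671 ± 334 (SD, n = 6). miR-379-5p fell from 2397 ± 286 to 695 ± 31.3 CPM, miR-127-3p from 1446 ± 333 to 398 ± 119, miR-411-5p from 1098 ± 184 to 391 ± 34.2, and miR-434-3p from 829 ± 152 to 382 ± 45.8. miR-300-5p (-0.42) and miR-668-3p (-0.26), both under a mean CPM of 3, did not pass over all names. Without the arms of the title hairpins, 57 of 59 members were lower, with a median of -1.66. The camera adjusted p of the whole list was 1.4e-13, and the adjusted p was 0.177 with an estimated correlation. The muscle and liver miRNAs miR-206-3p and miR-122-5p were also lower at day 8.

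**Figure D3:**
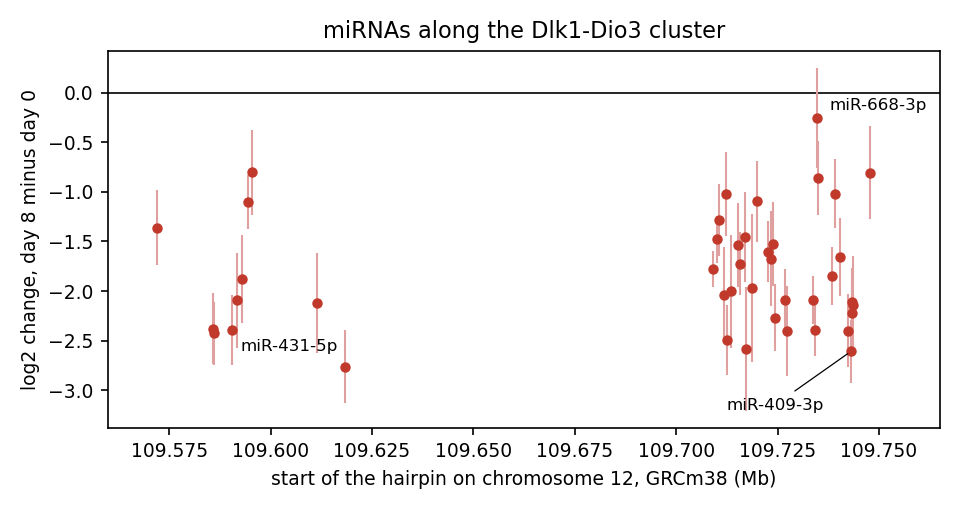
Log2 change of CPM + 1 from day 0 to day 8 (y axis, n = 6 libraries at each age) for the more abundant arm of 42 hairpins of the Dlk1-Dio3 cluster, at the start of each hairpin on chromosome 12 (x axis, Mb, GRCm38), with 95% confidence intervals from limma as bars. The changes run from -2.76 to -0.26 (miR-668-3p) over 176 kb.

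Other imprinted miRNAs fell as well: 10 of 10 tested members were lower, also when adjusted over the list alone, with a median log2 change of -1.48. These members, too, are arms of fewer hairpins. miR-335-5p, from an intron of Mest, fell from 18839.5 ± 1742 to 8276 ± 1739 CPM (SD, n = 6) and miR-335-3p from 1007 ± 83.4 to 297 ± 60.1. miR-296-3p fell from 167 ± 12.9 to 44.7 ± 10.7 CPM and miR-298-5p from 292 ± 23.1 to 106 ± 29.1. The camera adjusted p was 0.00197, and the adjusted p was 0.0665 with an estimated correlation.

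Of 21 tested members of the miR-17-92 and paralog clusters, which are tied to cell proliferation, 14 fell and 0 rose, while with TMM factors 13 were lower and 2 higher. The counts were 14 and 0 adjusted over the list alone as well, and the median log2 change was -0.76. miR-92a-1-5p, which fell, is not among the 21, since its name carries a locus number. miR-20a-5p went from 16255 ± 1306 to 5618 ± 775 CPM (SD, n = 6), miR-93-5p from 18139 ± 1162 to 9329 ± 1220, miR-25-3p from 13691 ± 743 to 8094 ± 658 and miR-19b-3p from 8885 ± 996 to 6367 ± 1333. The last had a log2 change of -0.11 with TMM factors, not past the threshold, and 0.11 with upper quartile factors. The camera adjusted p was 0.0113, and the adjusted p was 0.0932 with an estimated correlation. In the cluster of miR-322 and miR-503 8 of 11 members fell and 0 rose, while with TMM factors 5 were lower and 2 higher. As many fell when adjusted over the list alone, with a median of -0.71 and a camera adjusted p of 0.157. miR-503-5p went from 2349 ± 219 to 971 ± 183 CPM, while miR-322-5p was at 16612.5 ± 1471 and 17108 ± 1469 CPM, a log2 change of 0.04 that was 0.43 and past the threshold with TMM factors.

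The miR-30 family rose: 8 of 9 members were higher, also when adjusted over the list alone, and miR-30b-3p fell from 59.1 ± 8.73 to 30.4 ± 2.13 CPM (SD, n = 6). miR-30c-5p rose from 6442 ± 540 to 13140.4 ± 1176 CPM and miR-30d-5p from 2399 ± 293 to 6630.3 ± 1361. The median log2 change of the family was 0.91, the camera adjusted p was 1.1e-05, and it was the 1 list past the threshold with an estimated correlation (adjusted p = 0.0279 with an estimated correlation). In the family of miR-192, miR-194 and miR-215 3 of 4 members rose, also adjusted over the list alone, with a median of 1.61 and a camera adjusted p of 0.00197 (adjusted p = 0.0932 with an estimated correlation). miR-192-3p rose from 27.5 ± 4.31 to 78.9 ± 10.6 CPM. miR-215-5p was at 19.1 ± 18.0 and 5.29 ± 10.5 CPM, with a log2 change of -1.84 (limma adjusted p = 0.0929). It passed the threshold without day 0 replicate 1 (-2.46) and without day 8 replicate 2 (-2.48).

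The miR-200 family of epithelial miRNAs was mixed, with 3 of 9 members higher and 4 lower, counts that held when adjusted over the list alone. miR-200a-3p rose from 9774 ± 548 to 16003 ± 1080 CPM (SD, n = 6) and miR-200b-3p from 9340.3 ± 581 to 11643 ± 993, and miR-429-3p rose from 13083 ± 642 to 15326 ± 1004. miR-141-3p was at 2865 ± 327 and 3445 ± 618 CPM, and passed the threshold without day 0 replicate 2 (log2 change 0.30), day 8 replicate 3 (0.33) or day 8 replicate 4 (0.31), and with TMM factors (0.64). The median was -0.15 (-0.24 without day 8 replicate 3, -0.03 without day 8 replicate 2) while camera pointed up (adjusted p = 0.236), and with TMM factors 4 members were higher and 0 lower. The let-7 family, with 2 of 16 members higher and 6 lower (the same adjusted over the list alone), also turned with the scaling. let-7c-5p rose from 31560 ± 3287 to 38806 ± 3931 CPM and let-7i-5p fell from 34937.5 ± 2386 to 22325 ± 860, while let-7a-5p had a change of -0.27, and 0.12 with TMM factors, not past the threshold. The let-7 median was 0.02, the mean -0.06 and the camera adjusted p 0.419 in the upward direction, whereas fry pointed down. With TMM factors 9 members were higher and 3 lower. The median was -0.01 without day 0 replicate 1, -0.00 without day 8 replicate 4, and -0.30 with only the more abundant arm of each hairpin.

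Of 8 miRNAs embedded in Hox clusters, 5 were lower and 0 higher with a median of -0.42, but with upper quartile factors 3 were higher and 0 lower with a median of 0.15. The counts were also 5 and 0 adjusted over the list alone, and the camera adjusted p was 0.236. miR-196a-5p fell from 12644 ± 971 to 7504 ± 365 CPM (SD, n = 6), miR-10b-5p was at 25888 ± 2991 and 22876 ± 4211, and miR-196b-5p at 11418 ± 830 and 10781 ± 1076, with a log2 change of -0.09 that was 0.30 and past the threshold with TMM factors. miR-10b-5p passed without day 8 replicate 3 (log2 change -0.28). In the family of miR-34 and miR-449 miR-34a-5p rose from 836 ± 56.9 to 1353 ± 238 CPM. miR-34c-5p fell from 289 ± 13.8 to 171 ± 15.3 and miR-449a-5p from 38.8 ± 4.30 to 22.8 ± 4.33. Of its 6 members 1 was higher and 4 were lower, while with upper quartile factors 2 were higher and 0 lower. The counts were the same adjusted over the list alone, with a camera adjusted p of 0.639.

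Endothelial miRNAs had 3 of 7 members higher and 0 lower, also adjusted over the list alone, with a median of 0.32, while with TMM factors 6 were higher and 0 lower. miR-126a-5p rose from 20104 ± 2364 to 32021 ± 5030 CPM (SD, n = 6), and miR-221-3p was at 1852 ± 197 and 2003 ± 197, passing with TMM factors (log2 change 0.50). The camera adjusted p was 0.00997, and the adjusted p was 0.0665 with an estimated correlation. Leukocyte miRNAs had 4 of 8 members higher and 1 lower, also adjusted over the list alone, and 6 higher and 1 lower with TMM factors. miR-150-5p rose from 173 ± 29.6 to 408 ± 95.1 CPM and miR-146a-5p from 1251 ± 81.1 to 1658 ± 131, while miR-155-5p, singled out after its values were seen, fell from 161 ± 25.6 to 73.4 ± 11.5. The median was 0.38 and the camera adjusted p 0.0347, and the adjusted p was 0.0932 with an estimated correlation.

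Mesenchymal miRNAs had 4 of 12 members higher and 3 lower (5 and 3 adjusted over the list alone), with a median of 0.08, a mean of -0.14 and a camera adjusted p of 0.167 in the upward direction. With TMM factors 7 were higher and 2 lower with a median of 0.47, and with only the more abundant arm of each hairpin the median was -0.03. miR-143-3p rose from 30851 ± 2072 to 39732 ± 2441 CPM (SD, n = 6), and miR-199a-5p was at 5274 ± 452 and 4500 ± 1043. miR-214-3p, singled out after its values were seen, fell from 226 ± 50.7 to 55.6 ± 15.1. All 5 tested striated muscle miRNAs fell, also adjusted over the list alone, with a median of -1.23 and a camera adjusted p of 0.167, and 3 were lower with TMM factors. Among them miR-1a-3p went from 847 ± 362 to 422 ± 32.5 CPM, with a log2 change of -0.89 that was -0.50 and not past the threshold with TMM factors, and miR-133a-3p from 112 ± 43.9 to 28.6 ± 5.44. Of 6 miRNAs of other organs, 2 fell, both arms of miR-122, and miR-375-3p rose from 58.9 ± 6.77 to 88.8 ± 24.6 CPM. These counts were the same adjusted over the list alone. The median was -0.35, while camera pointed up (adjusted p = 0.940). Of 3 erythroid miRNAs 0 passed over all names or adjusted over the list alone. At an unadjusted p under 0.05 they numbered 0 as well, and by edgeR with upper quartile factors or by voom 1. Their median was -0.25, while camera pointed up (adjusted p = 0.624), and it was 0.14 with TMM factors and 0.09 without day 0 replicate 6, as was the change of miR-451a in each case. miR-451a was at 233 ± 193 and 169 ± 53.6 CPM. The list of both title miRNAs, chosen by the study, had 2 of 2 lower, also adjusted over the list alone, and a camera adjusted p of 0.0803, so this count is not independent evidence.

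**Figure D4:**
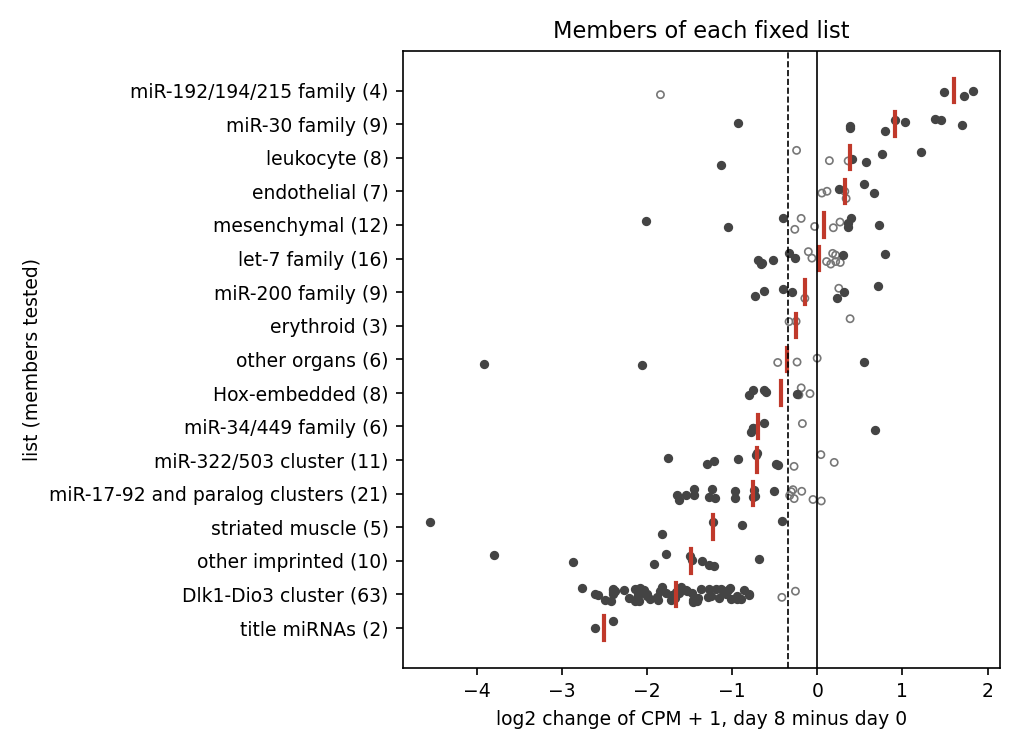
Log2 change of CPM + 1 from day 0 to day 8 (x axis, n = 6 libraries at each age) for the members of each fixed list with at least 2 tested members (y axis, number tested in brackets), where each point is a miRNA, filled if its limma adjusted p over all names was under 0.05, red bars are list medians, and the dashed line is the median of all miRNAs, -0.34. Medians run from -2.50 for the title miRNAs to 1.61 for the family of miR-192, miR-194 and miR-215, and those of the miR-200, erythroid, Hox and other organ lists turn positive under at least 1 other scaling.

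The fourth comparison asked whether both arms of a hairpin changed alike. The ratio of 5p to 3p CPM changed in 47 of 72 hairpins (limma, adjusted p under 0.05). For miR-409 the log2 ratio went from -1.61 ± 0.0971 to -0.71 ± 0.295 (SD, n = 6), so that the 3p arm, named in the title, lost more than the 5p arm (adjusted p = 4.2e-05). The hairpins that follow were chosen after their values were seen. The ratio of miR-30b rose from 4.93 ± 0.336 to 6.77 ± 0.277 and that of miR-125a from 8.05 ± 0.296 to 9.55 ± 0.388, while that of miR-27a fell from -4.71 ± 0.321 to -6.22 ± 0.216. Of the 47 changes, 26 went towards the more abundant arm and 21 towards the less abundant one. The count depends on the minimum CPM: 72 of 112 hairpins changed at a minimum of 5 and 26 of 34 at a minimum of 100.

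The last comparison concerned library composition. The 10 most abundant miRNAs held 49.9% ± 0.903 of the reads at day 0 and 50.5% ± 0.605 at day 8 (SD, n = 6). The difference of 0.614 percentage points did not pass the exact permutation test (two-sided p = 0.190), and for the 5 most abundant miRNAs it was -0.734 points (exact permutation p = 0.175).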

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

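The tests on muscle, on scaling, on the mesenchymal list and on sequencing depth, and the splits for all miRNAs, were chosen only after the results they bear on had been seen.

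Of 164 groups of 6 libraries checked for a single library far from the others, 8 stood out. Chance gives about 1 in 20 groups, so this is about as many as chance alone would give. Day 0 replicate 1 had low values for miR-30e-5p, at 2982 CPM against 3894 to 4250.4 in the other 5, and for miR-130b-3p, at 599 against 800.3 to 895. Day 0 replicate 6 had 285 CPM of miR-204-5p against 367 to 409.6, and 619.8 CPM of miR-451a, an erythroid miRNA, against 100.3 to 191. Day 0 replicate 2 had 12285.5 CPM of miR-25-3p against 13683 to 14441. Day 8 replicate 3 had 286 CPM of miR-541-5p against 137 to 181, and 200.1 CPM of miR-222-3p against 95.7 to 109. Day 8 replicate 2 had 26.6 CPM of miR-215-5p against 0.509 to 2.52.

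The first pattern weighed was the fall of the Dlk1-Dio3 cluster, which came with lower miR-206-3p and miR-122-5p. Muscle carried along with the day 0 kidneys was argued against as the whole cause: the summed cluster CPM above the day 8 mean varied 1.80-fold over the 6 day 0 libraries, while that of miR-206-3p varied 8.34-fold. A part from muscle stays open, since day 0 replicates 2 and 5, with the lowest miR-206-3p above the day 8 mean (45.7 and 76.6 CPM), also had the lowest cluster values (6364 and 6827 CPM, against 8491 to 11428 in the other 4). Day 0 replicate 2 had the most miR-122-5p (3284 CPM), while replicate 4, with the highest cluster value, had 910 CPM. These values argue against liver carried along as the whole cause. A part from liver stays open, since replicate 5 had the least miR-122-5p (478 CPM) and a low cluster value. Scaling was argued against as the whole cause, since a single factor per library moves all names by about the same amount. The cluster's median log2 change was -1.66 against -0.34 for all names, and -1.29 with TMM factors. Such factors centre the changes by construction, so a change of the cluster per cell was not settled. The mesenchymal list's median of 0.079 (interquartile range 0.659) argues only against an even loss of all cells that its members mark. About the cluster's own -1.66 would be needed if both came from the same cells alone, which was not tested. The members moved apart, with 4 of 12 higher and 3 lower, so their median cannot stand for a single cell fraction. Loss of some mesenchymal cells therefore stays open. A lower output of the cluster with age, or fewer cells of a type the lists do not cover, may account for the fall, and neither was tested.

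The second pattern was the excess of lower calls, 272 against 93. That the 20 most abundant names took more of the day 8 reads was argued against, since they held 66.98% of the reads at day 0 and 67.39% at day 8. Without them in the library totals the median log2 change was -0.356, against -0.367 for the same names with them. With shares this close, leaving them out could move the median only a little. Other abundant names that rose were not covered by this test. Scaling to the library total cannot be told apart from a true excess. With TMM factors 53.02% of the calls were lower, but such factors centre the changes by construction, and the median log2 change differed by abundance, from -0.59 for names with a mean CPM between 100 and 1000 to 0.01 above 1000. No measure of miRNA per cell was used here that could settle it, and the difference in age stays among the open explanations as untested.

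The third pattern was in day 0 replicate 6, where 7 names lay at least 2.5 log2 units above the mean log2(CPM + 1) of the other 5 day 0 libraries, a limit set after the values were seen. They include miR-6238 at 1994 CPM, miR-6239 at 1587 and miR-6240 at 787, and together the 7 held 0.475% of that library's reads against 0.00696% in the others. Not all 7 were particular to it: miR-1187 was at 35.9 CPM there and reached 31.2 in a day 8 library. For miR-1195 the values were 84.8 CPM there and up to 15.3 at day 8. Shallow sequencing was argued against by a median of 819 reads behind the 7 names in day 0 replicate 6. Fragments of ribosomal RNA could not be told apart from other sources: 0 of the 7 hairpins shared 20 bases with an annotated ribosomal transcript, but so did 0 of 359 other hairpins, so the search was void. No biological explanation was tested, because the labels give none for a single library.

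A random assignment of the 12 libraries to the ages was argued against for the number of calls. Of the 462 splits into 6 and 6, 100 were drawn. Only 1 of these, the real one, gave as many as 365 calls, and the highest of the others gave 166. The same holds for the arm balance, where 1 of 100 splits, again the real one, gave as many as 47 hairpins and the highest of the others gave 17. The splits treat the libraries as independent, which the labels do not state. They cannot tell age from a litter or batch that went with it.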

How the results depend on the processing

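Chosen only after the data were seen were edgeR with TMM factors on reads, CPM rescaled by TMM or RLE factors, and the fit without both day 0 replicate 6 and day 8 replicate 3. The total of 365 calls was between 362 and 369 with other scalings, tools on recovered reads and pseudocounts. It was 402 of 1652 names with no filter, 256 of 359 with a mean CPM of at least 10, and 378 without both libraries that stood apart. Leaving out 1 library at a time gave 346 to 379 calls, 89 to 98 higher and 254 to 281 lower, with 7 lists past the threshold each time, 40 to 45 hairpins, and a difference of 0.363 to 0.886 points in the share of the 10 most abundant miRNAs. miR-409-3p kept its direction and its call under every alternative, between -2.68 and -2.08, as did miR-431-5p, between -2.50 and -1.83. At a fold of at least 2, a stricter criterion by construction, 162 miRNAs were called, 25 higher and 137 lower.

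The number of higher calls went from 93 to 180 with DESeq2, 174 with voom, 177, 213 and 173 with edgeR on RLE, upper quartile and TMM factors, and 171 and 175 with CPM rescaled by TMM and RLE factors. Lower calls went from 272 to 155 with upper quartile factors. Such factors shift every change by about the same amount, by construction. Of 17 lists, 7 passed camera, 1 passed with an estimated correlation and 14 passed fry, which asks a different question. With only the more abundant arm of each hairpin, the miR-17-92 list (adjusted p = 0.0691) and the endothelial list (0.103) lost their calls. The median of the miR-200 list turned from -0.15 to 0.25 there, since the less abundant arms, 3 of 4 of which had fallen, were left out by construction. The arm test called 72 hairpins at a minimum CPM of 5 and 26 at 100, since the minimum sets how many are tested.

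Of 77 named miRNAs, 46 had the same direction and side of the threshold under every alternative. Over 1924 values, 38 lost the call, 70 gained one and 100, in 15 miRNAs, turned direction. Of these, 29 turned to a call past the threshold, and in 49 neither value passed it. Leaving out 1 library gave 8 lost calls, all of miR-10a-5p, 10 gained and 7 turned: miR-9-5p ran from -0.076 to 0.11, miR-152-3p from -0.067 to 0.035 and miR-451a from -0.43 to 0.090, none past the threshold. Without both libraries that stood apart miR-152-3p was at 0.0038. These turned from values near 0 or, for miR-451a, without day 0 replicate 6, which had its highest value, and the cause was not tested. The other turned values come from scalings that raise day 8 against day 0, by construction.

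With DESeq2 the log2 changes were 0.17 for miR-16-5p, 0.18 for miR-10a-5p, 0.22 for miR-26a-5p, 0.16 for let-7a-5p, 0.015 for miR-542-3p, 0.23 for miR-10b-5p, 0.35 for miR-196b-5p, 0.41 for miR-152-3p, 0.21 for miR-199a-5p, 0.12 for miR-144-5p, 0.39 for miR-9-5p, 0.20 for miR-9-3p and 0.25 for miR-34b-5p. With edgeR and RLE factors each of these 13 had the same rounded value. voom gave 0.14 for miR-16-5p, miR-10a-5p and miR-199a-5p, 0.20 for miR-26a-5p and miR-34b-5p, 0.13 for let-7a-5p, 0.19 for miR-10b-5p, 0.30 for miR-196b-5p, 0.36 for miR-152-3p, 0.15 for miR-451a, 0.070 for miR-144-5p, 0.39 for miR-9-5p and 0.16 for miR-9-3p.

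With edgeR and upper quartile factors the changes were 0.31 for miR-16-5p and let-7a-5p, 0.34 for miR-10a-5p, 0.37 for miR-26a-5p, 0.11 for miR-19b-3p and miR-451a, 0.16 for miR-542-3p, 0.39 for miR-10b-5p, 0.49 for miR-196b-5p, 0.55 for miR-152-3p, 0.36 for miR-199a-5p, 0.25 for miR-144-5p, 0.53 for miR-9-5p, 0.35 for miR-9-3p and 0.40 for miR-34b-5p. With edgeR and TMM factors they were 0.13 for miR-16-5p and let-7a-5p, 0.16 for miR-10a-5p, miR-199a-5p and miR-9-3p, 0.18 for miR-26a-5p, 0.21 for miR-10b-5p and miR-34b-5p, 0.31 for miR-196b-5p, 0.37 for miR-152-3p, 0.065 for miR-144-5p and 0.36 for miR-9-5p.

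CPM rescaled by TMM factors gave 0.13 for miR-16-5p and miR-199a-5p, 0.15 for miR-10a-5p and miR-9-3p, 0.19 for miR-26a-5p, 0.12 for let-7a-5p, 0.20 for miR-10b-5p and miR-34b-5p, 0.30 for miR-196b-5p, 0.36 for miR-152-3p, 0.14 for miR-451a, 0.056 for miR-144-5p and 0.39 for miR-9-5p. CPM rescaled by RLE factors gave 0.16 for miR-16-5p and miR-199a-5p, 0.18 for miR-10a-5p and miR-9-3p, 0.22 for miR-26a-5p, 0.15 for let-7a-5p, 0.23 for miR-10b-5p and miR-34b-5p, 0.33 for miR-196b-5p, 0.39 for miR-152-3p, 0.17 for miR-451a, 0.087 for miR-144-5p and 0.42 for miR-9-5p.

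Over 306 list medians, which leave out the tools on recovered reads, 275 had the same direction and side of the threshold, 10 lost the call, 9 gained one and 12, in 4 lists, turned direction, 3 of these with 1 library left out. The miR-200 median was 0.24 and 0.27 with CPM rescaled by TMM and RLE factors, and the erythroid median 0.14 and 0.17. On recovered reads the miR-200 and erythroid medians were also positive with every setting but total count scaling, the Hox median was 0.0040 with DESeq2, 0.0037 with RLE and 0.15 with upper quartile factors, and that of other organs 0.12 with upper quartile factors. With only the more abundant arm of each hairpin, the let-7 median was -0.30, the mesenchymal median -0.030 and the erythroid median 0.069, since the members differ by construction. Leaving out 1 library gave let-7 medians from -0.015 to 0.10 and erythroid medians from -0.43 to 0.090, and without both libraries that stood apart the let-7 median was -0.010; the cause was not tested. The difference in the share of the most abundant miRNAs, 0.614 points for 10 miRNAs, was -0.734 for 5, since other miRNAs are summed by construction. Depth limits mainly names near 1 CPM: in the shallowest library, with 3.37 M reads (M, 1000000), 1 CPM is about 3 reads.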

Other observations

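The miRNAs in the next paragraph, and the share of shuffles with the strongest kind of site, were chosen only after their values were seen, while the tests on seed sites and on position along the cluster were written before.

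Outside the fixed lists, the miR-29 family, known to act on mRNAs of collagens and other matrix proteins, was higher at day 8 in 6 of 6 tested members. miR-29a-3p rose from 239 ± 38.1 to 507 ± 64.4 CPM (SD, n = 6 at each age), a log2 change of 1.09 with a limma adjusted p of 1.7e-06, and miR-29c-3p from 428 ± 39.7 to 634 ± 44.8. miR-101a-3p rose from 928 ± 88.9 to 2051 ± 369 CPM, and miR-497a-5p, made from the same transcript as miR-195a-5p, from 516 ± 75.2 to 1045 ± 202. Among falls, miR-205-5p, an epithelial miRNA, went from 949 ± 193 to 331 ± 85.4 CPM, a log2 change of -1.53. miR-132-3p, induced by neuronal activity and CREB, went from 309 ± 54.9 to 111 ± 27.9, and miR-301b-3p, which shares a seed with miR-130b-3p, from 419 ± 39.0 to 153 ± 21.2. miR-181d-5p went from 643 ± 109.9 to 258 ± 87.5. With TMM factors the log2 changes were 1.48 for miR-29a-3p and -1.14 for miR-205-5p.

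A hypothesis set by the title is that the receptor mRNA carries seed sites of both title miRNAs above chance in the Nr3c2 3 prime UTR. In the longest annotated 3′ UTR of Nr3c2, 2482 bases long, there were 2 such sites, 1 for each miRNA and both of the strongest kind (8 bases). The site of miR-409-3p lies on chromosome 8 at 77244406 to 77244413 (GRCm38), at position 1876 of the 3′ UTR, and that of miR-431-5p at 77244123 to 77244130, at position 1593. Of 1000 shuffles that keep the dinucleotides, 45.6% held as many sites for miR-409-3p, 28.4% as many for miR-431-5p and 24.8% as many in total, so the count cannot be told apart from chance. An 8-base site of miR-409-3p was in 6.5% of shuffles, one of miR-431-5p in 5.4%, and both in 0.4%. Because this share was computed after the sites had been seen, it may only serve as a hypothesis beside the test's value of 2 sites, and neither the mRNA nor the protein of the receptor was measured here.

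A second hypothesis was that the fall of the Dlk1-Dio3 miRNAs changed with position along the cluster. Across 42 hairpins over 176 kb, Spearman's rho of position and log2 change was 0.011 (permutation p = 0.945) and Pearson's r was 0.098 (permutation p = 0.538). Without the 2 hairpins farthest from the median position, rho was 0.012 and r was 0.104. These are 2 relations across hairpins of the same libraries, which are not independent replicates. The rho lies within 0.1 of 0, which by the rule set beforehand argues against a steady gradient of this kind. With 42 hairpins a weaker gradient cannot be excluded, and the 1 added to CPM damps the changes of low names.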
